A study of Homo sapiens with 2 samples.

How the data were processed

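Chromatin of K562, an established human erythroleukemic cell line that carries the BCR-ABL1 fusion, was immunoprecipitated with an antibody against ARID4B, a DNA-binding subunit of the SIN3-HDAC co-repressor complex. The series holds 1 ChIP library and 1 input library, and the input DNA served as the control per the labels. There were no replicates of either kind, so no p-value was computed and no difference has a replicate check. The numbers of reads per library are not given in the sources used here, so the sequencing depth is unknown.

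Reads were aligned with BWA to hg19 (GRCh37) and peaks were called with MACS, per the submitters' processing notes. The versions, the peak threshold and the fragment extension are not given in the sources used here. The deposited peak list holds the summit position, summit height, start and end of each interval. The summit height is a ChIP signal that the authors deposited as whole numbers. Its scaling to depth is not stated, so it was used only to describe, rank and filter peaks within this list. The deposited gene table gives, per the file headers, the number of intervals assigned to each gene, the mean signal of those intervals and the distance from each summit to the gene start. It lists only genes with at least 1 interval in the gene or up to about 10 kb away, with 1 start per gene. A list of links to signal tracks was not used.

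The 2 tables were checked against each other. All 15013 pairs of gene and interval had a distance equal to the one recomputed from the positions, and all 9860 mean signals equalled the mean of the interval heights within 0.06. Of the summit positions, 96.7% were multiples of 16 bp, which sets their resolution. Summits and gene positions are given as the files give them, on hg19, and interval starts are counted from 1.

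A promoter peak was a peak whose summit lay within 1 kb of a listed gene start. The remaining peaks were divided into those inside a listed gene, those in the flank of a listed gene and those with no listed gene. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Differences in height are given with percentile bootstrap intervals over peaks (1000 resamples, seed 1). Peaks of 1 library are not replicates, and these intervals do not cover variation between cultures.

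For 24 gene lists, the share of members with a promoter peak was set beside that of all 20056 protein-coding genes in the RefSeq names of GRCh38.p14. Of these lists, 13 were written as symbols and 11 as name patterns. That table was used for names, biotypes and gene order, and none of its coordinates are given. Of the 9860 genes listed, 9485 were matched to it by gene identifier and 375 were not. The gene table carries older symbols, such as LGTN for EIF2D, so its annotation may lack genes named since. Such genes could not be listed and counted as having no peak, which would lower the shares. Each list count was given a percentile among 10000 random lists of the same size drawn from the protein-coding genes. Matching on gene length had been planned, but the gene table gives lengths only for genes near peaks, so these random lists were not matched. The percentile describes these libraries and is not a test across replicates. The snoRNA and microRNA groups have shares without a percentile, since most or all of their members are not protein-coding. The microRNA group was taken by name, holds host genes such as MIR17HG, and has 9 members with a protein-coding entry among 2014.

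The list percentile was tested on simulated data with 200 lists of 30 genes among 20056. Of lists with no difference, 2.5% fell above the upper bound of the middle 95% and 2.5% below the lower bound. These lists were drawn as the random lists were, so their result checks the calculation only. Of lists with a doubled share, 93% fell above the upper bound. Groups of neighbouring genes that share a peak were not simulated. Where promoter peaks were simulated to depend on gene length and the lists held long genes, the unmatched percentile, the one used for promoter peaks, put 89% of lists above the bound with no other difference, and the matched version 2.5%. The promoter percentiles are therefore not corrected for gene length. All 500 simulated distances were recovered. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.

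The lists, the windows, the rule for named genes and most alternatives were fixed before the data were examined. The rule took KIT, KITLG and the 8 Src-family kinases; 12 genes of the SIN3-HDAC complex and of erythroid and progenitor control; the 10 symbols with the highest promoter peak; the 5 symbols with the most peaks, ties included; the 3 members of each list with the highest promoter peak; and list members without a promoter peak where these were 5 or fewer. The results of some of these genes are not reported here. Alternatives were other windows, peaks with a height of at least 27 or at least 46 (the median and the 90th percentile of all heights), peaks merged when closer than 1 kb, any assigned peak, peak width in place of height, and peaks outside chromosomes 9 and 22. Chosen after the data were seen were the alternatives that counted only the start nearest to a summit, that used current symbols only, and that left out a run of tall peaks on chromosome 22. That run was defined by a median height over 7 neighbouring promoter peaks of at least 2 times the median of all promoter peaks, joined across gaps of up to 2 promoter peaks.

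Shifting the peaks along the chromosomes, planned as a control for their position, was not done, because the table lists only genes near peaks and the shifted peaks would find too few starts. The ratio of ChIP to input at peaks was not computed, because the tables used give no input values. The overlap of the peak list with the regions of the gene table was not computed, because that table names intervals and gives no coordinates of its own for them.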

Results

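ARID4B occupancy was measured by ChIP-seq in K562 cells, a human erythroleukemic line, with 1 ChIP library and 1 input library. The title of the series places the experiment in a study of the KIT-Src pathway and the differentiation of haematopoietic progenitors. The question put to the data was which genes carried ARID4B at or near their starts. The list held 8819 peaks on 23 chromosomes (1 to 22 and X), covering 8.42 Mb in all. Summit heights, in the authors' units, ran from 13 to 316, with a median of 27 and quartiles of 22 and 34. Interval widths had a median of 828 bp and quartiles of 598 and 1164 bp. Height and width were related across peaks (Spearman's rho 0.638, with peaks not being independent replicates). Genes were listed near 8389 peaks, and no gene was listed for the other 430. In all, 9860 genes were listed, of which 6433 had 1 peak and 3427 had 2 or more.

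ARID4B lay mostly at gene starts. The summit was within 1 kb of a listed gene start for 6515 of the 8819 peaks (73.9%, exact 95% interval 72.9 to 74.8%) and within 250 bp for 45.5% (44.5 to 46.6%). A further 1339 peaks (15.2%) lay inside a listed gene, 535 (6.07%) in a gene's flank and 430 (4.88%) near no listed gene. Only genes near peaks have a listed start, so no chance level for these shares could be computed. Summits lay on the transcribed side of the start more often than upstream of it: 4630 of the 6515 promoter summits (71.1%) were downstream, and their median position was 100 bp downstream (bootstrap 95% interval 94 to 105 bp).

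**Figure D1:**
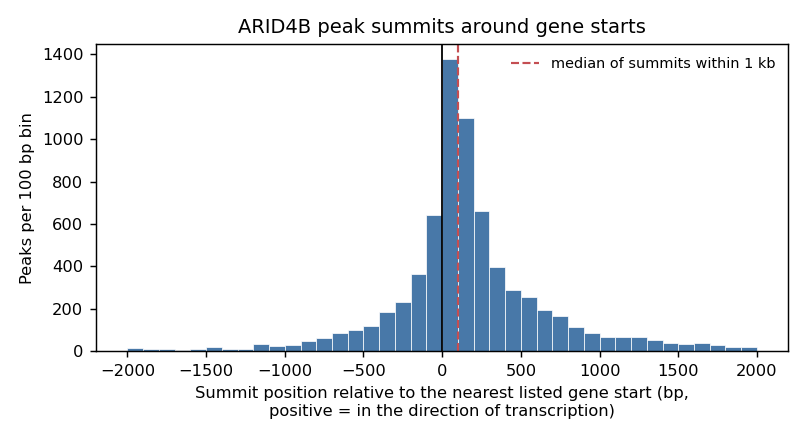
Number of ARID4B peaks (y axis, per 100 bp) by the position of the summit relative to the nearest listed gene start (x axis, bp, positive in the direction of transcription). The bars are highest just downstream of the start (solid line), and the dashed line marks the median of +100 bp of the 6515 summits within 1 kb.

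Promoter peaks were taller than the rest. Their median height was 28 (quartiles 23 and 36) against 24 in the 2304 other peaks, a difference of 4 (bootstrap 95% interval 4 to 5) and a ratio of 1.17 (1.17 to 1.22). Peaks inside genes had a median of 24 and those with no listed gene 23. With the peaks ranked by height and split into 10 equal groups, the share at promoters went from 59.4% (56.1 to 62.7%) in the lowest group to 92.2% (90.2 to 93.9%) in the highest. The highest peak with no listed gene was at chromosome 1, 16969172 to 16971565, with a height of 156.

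The highest promoter peak of all was at NUP214, a nuclear pore gene on chromosome 9 (gene 134000981 to 134109091, plus strand). Its summit lay 43 bp downstream of the start in an interval from 133999930 to 134005533, with a height of 316. The interval was 5604 bp wide, against a median of 876 bp for promoter peaks. Heights here and below were not corrected for copy number, which was not analysed. Among the other high promoter peaks, that of CRBN, the substrate receptor of a ubiquitin ligase, had a height of 201 on chromosome 3 (interval 3220143 to 3221814). PPIL2 on chromosome 22 (interval 22019257 to 22022076) had 181, and the shared start of NAGPA and LOC100507589 on chromosome 16 (interval 5082494 to 5084404) had 180. SUMF1, needed to activate sulfatases, had 167, LGTN (now EIF2D) 159 and CCDC132 (now VPS50) 155. PPIL2 lay in a run of 40 peaks on chromosome 22 between 18893856 and 22901600, picked for its tall promoter peaks. Heights in the run went from 25 to 181, with a median of 71 against 23 on the rest of the chromosome. The median width was 3848 bp against 631 bp.

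**Figure D2:**
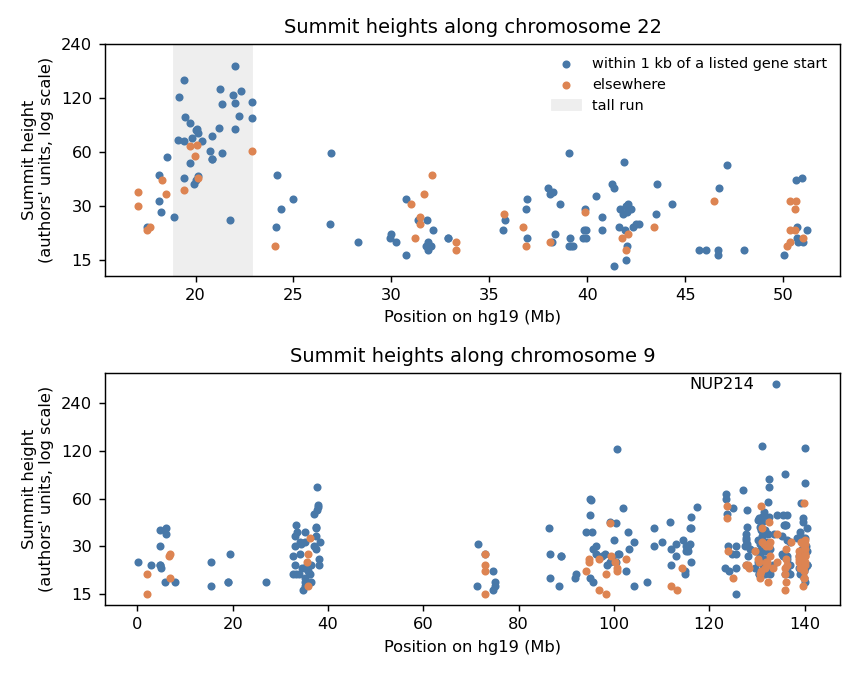
Summit height (y axis, authors' units, log scale) along chromosomes 22 and 9 (x axis, hg19, Mb), 1 point per peak, blue within 1 kb of a listed gene start and orange elsewhere. The shaded run on chromosome 22 holds 40 peaks with a median height of 71, and the point at 316 on chromosome 9 is the NUP214 promoter.

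The genes with the most assigned peaks were MIDN with 11 and KLF16, a zinc finger repressor, with 10, both on the short arm of chromosome 19. CIRBP, a cold-inducible RNA-binding protein gene, its antisense gene C19orf23 (now CIRBP-AS1) and REXO1 each had 8, on the same chromosome. CBFA2T3, a co-repressor gene of haematopoietic cells, and FAM38A (now PIEZO1, a mechanosensitive channel of red cells) each had 8 on chromosome 16. These genes shared intervals with their neighbours, and all 8 intervals of CIRBP were also assigned to C19orf23. The tallest of the CBFA2T3 peaks (height 113) was inside the gene, near its 3′ end, at 88941149 to 88942121, and the one at its start had 29.

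Neither KIT nor its ligand gene KITLG had a peak. No peak lay in the 1331 kb on chromosome 4 between the last summit listed for CHIC2 (54930656) and the first listed for TMEM165 (56262144), which flank KIT. No peak lay in the 1384 kb on chromosome 12 between those of TMTC3 (88535840) and WDR51B (89919856), which flank KITLG. Among the 8 Src-family kinase genes, YES1 and LYN had a promoter peak. The YES1 summit was 551 bp downstream of the start on chromosome 18 (interval 811303 to 813446, height 37), and that of LYN 862 bp downstream on chromosome 8 (56792819 to 56793575, height 23). LYN had another peak of height 23 inside the gene, 59710 bp from the start. SRC had 1 peak of height 19 inside the gene on chromosome 20, 40288 bp from its start (36013098 to 36013588). FYN, LCK, FGR and BLK were not listed with a peak. No peak lay between the listed neighbours of FYN, LCK or FGR, and 2 peaks with no listed gene lay in the 517 kb between those of BLK, MTMR9 and FDFT1.

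Of the 32 genes of KIT and Src signalling, 16 had a promoter peak (50%, 31.9 to 68.1%), against 6518 of 20056 protein-coding genes (32.5%, 31.9 to 33.2%). This count was at the 98.1st percentile of random lists. The share was 1.54 times that of all genes, and 1.0 times when the summit had to lie within 500 bp of the start. High promoter peaks of this group included those of PTPN11, the phosphatase SHP2 (height 49), and YES1 (37).

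ARID4B was found at most genes of its own complex, but not at these in particular. Of 28 SIN3-HDAC complex genes, 22 had a promoter peak (78.6%, 59.0 to 91.7%), more than in any of the 10000 random lists. Genes used by every cell, described below, had higher shares, from 83.8% for respiratory complex I to 95% for aminoacyl-tRNA synthetases. This order depended in part on how peaks were counted. When a peak counted only for its nearest start, SIN3-HDAC genes had 2.76 times the share of all genes. Cytosolic and mitochondrial ribosomal proteins were then still higher (2.90 each), but the proteasome (2.74), complex I (2.47) and the synthetases (2.46) were lower. A preference for the genes of the complex is therefore not shown. The highest were at BRMS1 (height 73), KDM5B (58) and KDM5A (40), the last pair encoding histone demethylases. The share was 2.42 times that of all genes, and 1.44 times among peaks with a height of at least 46, the 90th percentile of all heights. The ARID4B gene itself had 4 assigned peaks on chromosome 1, with one 172 bp downstream of its start (235490627 to 235491719, height 34). Its paralogue ARID4A had one 186 bp downstream of its start on chromosome 14 (58764989 to 58765886, height 28). SIN3A, the scaffold of the complex, had 5 assigned peaks on chromosome 15, of which the one at the start (540 bp downstream, 75746957 to 75748098) had a height of 28. HDAC2 had 1 peak, 263 bp downstream of its start (height 25). Both peaks assigned to HDAC1 lay beyond its end, 298 and 938 bp from the start of MARCKSL1. SIN3B had none, and none lay in the 237 kb between the summits of its listed neighbours TMEM38A and F2RL3.

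Among the gene lists, the highest shares with a promoter peak were at genes used by every cell. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 19 had a promoter peak (95%, 75.1 to 99.9%), and QARS had its peak elsewhere. Some of these peaks lay nearer to another listed start. With the nearest start only, the synthetases had 2.46 times the share of all genes, from 2.92. YARS (height 69, summit 705 bp from the start), VARS (66) and EPRS (64) had the highest. Mitochondrial ribosomal protein genes had one in 75 of 81 (92.6%, 84.6 to 97.2%), with MRPL40 at 152, MRPL9 at 106 and MRPL20 at 71; MRPL40 lies in the run on chromosome 22. Cytosolic ribosomal protein genes had one in 79 of 87 (90.8%, 82.7 to 95.9%), led by RPS18 (61), FAU (59) and RPL23A (59). Proteasome subunit genes had one in 35 of 41 (85.4%, 70.8 to 94.4%), led by PSMB7 (68), PSMD5 (60) and PSMB2 (55). Genes of respiratory complex I had one in 31 of 37 (83.8%, 68.0 to 93.8%), led by NDUFS7 (69), NDUFV1 (66) and NDUFA2 (63). Each of these 5 counts was above all 10000 random lists. Among peaks with a height of at least 46, the share was 7.71 times that of all genes for mitochondrial ribosomal proteins, 6.05 times for the synthetases and 4.90 times for complex I, from 2.85, 2.92 and 2.58 times among all peaks. It was 3.71 times for cytosolic ribosomal proteins, from 2.79, and 2.46 times for the proteasome, from 2.63.

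Among cell cycle genes of the RB-E2F axis, a promoter peak was present at 32 of 39 (82.1%, 66.5 to 92.5%), also above all random lists, with CCNE2 (58), CCNA2 (48) and the ribonucleotide reductase gene RRM2 (47) the highest. Genes of polycomb complexes and of histone and DNA methylation had one in 17 of 28 (60.7%, 40.6 to 78.5%; 99.9th percentile), led by PHF19 (48), MTF2 (41) and EZH2 (37). The share was 1.87 times that of all genes among all peaks, but 0.72 times, below it, among peaks with a height of at least 46. Histone genes had one in 34 of 71 (47.9%, 35.9 to 60.1%; 99.7th percentile). H2AC11, H2AC12 and H2BC11 (current symbols) had the highest, each 47. A peak within 1 kb of several starts counted for each of them. The histone share was 1.47 times that of all genes, and 1.29 times when a peak counted only for its nearest start. Genes with ZNF names had one in 276 of 714 (38.7%, 35.1 to 42.3%; 99.98th percentile). Their share was 1.19 times that of all genes, 1.03 times with a height of at least 27 and 1.13 times with at least 46. The highest were ZNF280B at 114, ZNF165 at 106 and ZNF212 at 103, and ZNF280B lies in the run on chromosome 22.

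**Figure D3:**
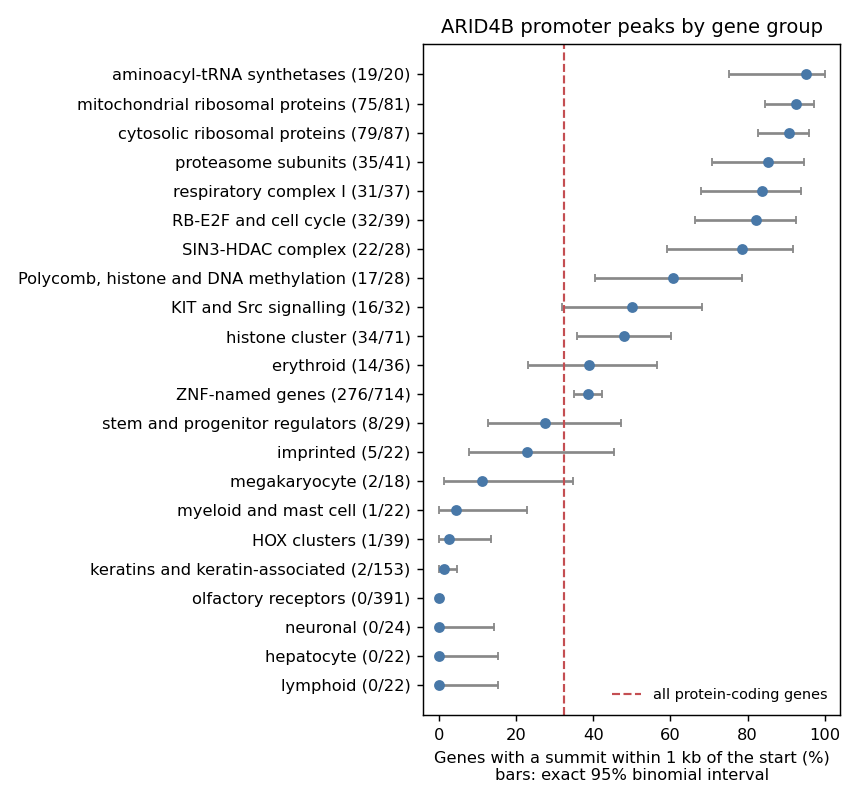
Share of genes with an ARID4B summit within 1 kb of the start (x axis, percent) for 22 gene groups, with the count and group size beside each name. Points are shares, bars exact 95% binomial intervals for counting error, and the dashed line the 32.5% of all protein-coding genes, with synthetases and ribosomal proteins at the top and lymphoid, hepatocyte and neuronal genes at 0.

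Erythroid and progenitor genes were occupied about as often as other genes, and with low peaks. Of 36 erythroid genes, 14 had a promoter peak (38.9%, 23.1 to 56.5%; 79.1st percentile), with a median height of 22.5. Their share was 1.2 times that of all genes, 0.79 times within 500 bp of the start, 0.54 times among peaks with a height of at least 27 and 0.56 times among those of at least 46. UROD, an enzyme of haem synthesis (53), the transferrin receptor gene TFRC (31) and BCL2L1 (28) had the highest. GATA1, the master regulator of erythroid genes, had a peak of height 17 at 598 bp upstream of its start on chromosome X (48644210 to 48644613), at the 3.02nd percentile of all heights. TAL1 had one of height 20 at 941 bp downstream of its start on chromosome 1 (47694241 to 47695072) and a taller one of 37 at 1789 bp upstream. KLF1 had none within 1 kb, but one of height 29 at 1729 bp downstream of its start on chromosome 19 (12995496 to 12996968). A peak of height 78 assigned to KLF1 lay 170 bp from the start of its neighbour GCDH.

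Of 29 stem and progenitor regulators, 8 had a promoter peak (27.6%, 12.7 to 47.2%; 29.4th percentile), 0.85 times the share of all genes and 0.50 times among peaks with a height of at least 27. The highest were at TCF3 (33), MYC (30) and CBFB (27). MYC had 4 assigned peaks on chromosome 8, at 1819 and 507 bp upstream and 197 and 2341 bp downstream of its start, with heights of 19, 25, 30 and 35. MYB had one of height 24 at 555 bp and one of 20 at 1899 bp downstream of its start on chromosome 6. GATA2 had 5 assigned peaks on chromosome 3, none within 1 kb of its own start, with heights of 18 to 22. One of these (128207423 to 128208301) lay 176 bp downstream of the start of LOC100506995.

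**Figure D4:**
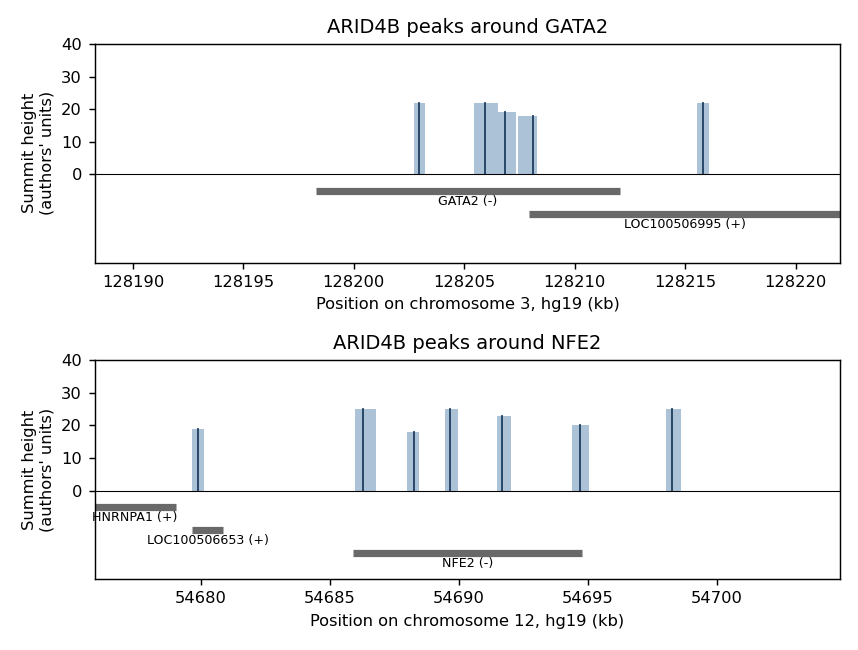
ARID4B intervals (light bars) and summits (dark lines) around GATA2 on chromosome 3 and NFE2 on chromosome 12, with summit height on the y axis (authors' units) and hg19 position on the x axis (kb); grey bars are genes listed in the deposited table, with the strand in brackets. At GATA2 the 5 peaks (heights 18 to 22) lie inside or upstream of the gene and none within 1 kb of its start.

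Genes of other lineages mostly lacked promoter peaks. Megakaryocyte genes had one in 2 of 18 (11.1%, 1.38 to 34.7%; 2.32nd percentile), at GP1BB (87) and NBEAL2 (23). GP1BB lies in the run on chromosome 22, and without that run the share was 0.17 times that of all genes, from 0.34. Among peaks with a height of at least 46 it was 1.12 times, with GP1BB included. Myeloid and mast cell genes had one in 22, at CEBPB (27; 4.55%, 0.12 to 22.8%; 0.15th percentile), although 6 of the 22 had some assigned peak. None of 22 lymphoid, 22 hepatocyte and 24 neuronal genes had a promoter peak, which allows shares of up to 15.4, 15.4 and 14.2% by the exact interval. These 3 counts were each at the 0.005th percentile. No hepatocyte gene had a peak assigned at all, while 3 lymphoid and 3 neuronal genes had one elsewhere.

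Of 39 HOX genes only HOXB9 had a promoter peak (height 30, 859 bp downstream), below all random lists, although 7 had some assigned peak. None of 391 olfactory receptor genes had one (upper bound 0.94%), and 2 of 153 keratin and keratin-associated genes did, KRT18 (25) and KRT19 (22; 1.31%, 0.16 to 4.64%). Both counts were below all random lists. Imprinted genes had one in 5 of 22 (22.7%, 7.82 to 45.4%; 16.4th percentile), led by CDKN1C (40), MKRN3 (35) and IGF2R (32). Among small RNA genes, 42 of 538 snoRNA genes had a summit within 1 kb (7.81%, 5.68 to 10.4%), led by SNORD48 (70), SNORD42B (59) and SNORA78 (58). Of 2014 genes with microRNA names, host genes included, 45 did (2.23%, 1.63 to 2.98%), led by MIR130B and MIR301B (81, the same peak, in the run on chromosome 22) and the host gene MIR17HG (63). When a peak counted only for its nearest start, these shares were 2.23% for snoRNA and 1.09% for microRNA genes. Small RNA genes missing from the authors' annotation would count here as lacking a summit, so these shares may be too low.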

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

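No paired analysis was possible because there was 1 library of each kind, and for the same reason no library could be left out. The depth of both libraries is unknown, so what it limits cannot be stated. The shifted-peak control, the ratio of ChIP to input and its rescaling, the overlap of the peak list with the gene table and, for promoter peaks, length-matched random lists were not run, because the tables used do not give the values they need. For the background, the unmatched and the protein-coding choices were the one used. Leaving out the run on chromosome 22, keeping only the start nearest to a summit and using current symbols only were chosen after the data were seen. Over 24 lists and 202 alternatives, the value stayed within the 95% interval of the reported one in 158, left it in 43, and in 1 crossed the share of all genes where the reported interval had excluded it. Where that interval included it, erythroid genes also crossed it, from 1.2 to 0.79 within 500 bp, 0.54 with a height of at least 27 and 0.56 with at least 46, and megakaryocyte genes from 0.34 to 1.12 with at least 46. Leaving out the run moved none of the 24 lists out of its interval, and current symbols none of the 10 lists they were run for. Merging peaks closer than 1 kb left 7687 peaks, and leaving out chromosomes 9 and 22 kept the height ratio within its interval; by width the ratio was 1.23.

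Fewer peaks enter the stricter sets by construction, and for the other differences the cause was not tested. The share of peaks at promoters was 60.9% within 500 bp, 81.7% within 2500 bp, 85.0% within 5000 bp, 88.5% within 10000 bp and 77.9% when any base of the peak counted. With a height of at least 27, the median, there were 4542 peaks, 82.4% of them at promoters, and 4118 protein-coding genes with a promoter peak. With a height of at least 46, the 90th percentile, there were 908 peaks, 92.2% of them at promoters, and 995 such genes.

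List values are ratios to the share of all protein-coding genes, and percentages for snoRNA and microRNA genes. With a height of at least 27 they were 1.03 for ZNF names, 4.38 for the synthetases, 3.30 for cytosolic and 3.73 for mitochondrial ribosomal proteins, 0.54 for erythroid genes, 2.06 for histones, 2.97 for the proteasome, 3.03 for complex I, 0 for keratins, 4.46% for snoRNA and 1.24% for microRNA. With a height of at least 46 the polycomb group went below the share of all genes, at 0.72. The others there were 0 for HOX, imprinted, keratin, myeloid and stem and progenitor genes, 1.44 for the SIN3-HDAC complex, 6.05 for the synthetases, 3.71 for cytosolic and 7.71 for mitochondrial ribosomal proteins, 0.56 for erythroid genes, 1.12 for megakaryocyte genes, 4.90 for complex I, 1.30% for snoRNA and 0.30% for microRNA. Within 500 bp, cytosolic and mitochondrial ribosomal proteins had 3.07 and 3.21, snoRNA 3.90% and microRNA 1.19%. Within 2500 bp, snoRNA had 19% and microRNA 4.02%. Within 10000 bp, the ribosomal groups had 2.48 and 2.47, snoRNA 33.8% and microRNA 7.65%. With any assigned peak, HOX had 0.42, the ribosomal groups 2.21 and 2.20, the proteasome 2.18, snoRNA 34.0% and microRNA 8.14%. With the nearest start only, snoRNA had 2.23% and microRNA 1.09%.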

Other observations

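Some tests were chosen only after the result was seen. These were the tests of the run on chromosome 22 and those of peaks away from starts at genes of other lineages. They also include those of haematopoietic genes restricted to genes with or without a promoter peak or to summits over 5 kb from a start. No biological explanation was tested through the design, which has 1 ChIP library and no second condition.

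Haematopoietic genes carried ARID4B peaks away from gene starts. Of the 31 erythroid genes and stem and progenitor regulators listed with a peak, 28 had at least 1 summit over 1 kb from every listed start. Among all 8544 listed protein-coding genes, 1921 did (22.5%). NFE2, an erythroid transcription factor gene, had 5 such peaks with heights of 18 to 25. RUNX1, needed for definitive haematopoiesis, had 5 with heights of 21 to 31, and ZFPM1, which encodes the GATA1 partner FOG1, had 5 with heights of 24 to 27. ANK1 and EPB41, which encode red cell membrane proteins, had 4 each. The tallest was in LYL1 on chromosome 19 (13209553 to 13212185), 2657 bp downstream of the start, with a height of 115. The genes named here outside the rule were chosen after their values were seen.

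The same measure was taken in other groups. Such a peak was listed at 13 of 23 polycomb and methylation genes (100th percentile of length-matched random lists) and at 9 of 22 genes of KIT and Src signalling (97.9th). RB-E2F genes had one in 12 of 36 (93.7th) and SIN3-HDAC complex genes in 5 of 26 (47.0th). Mitochondrial ribosomal protein genes had one in 6 of 76 (0.015th percentile), although 75 of 81 had a promoter peak. Few genes of other lineages were listed with a peak at all, but of those 24 (megakaryocyte, myeloid, lymphoid and neuronal genes and HOX genes), 13 had one away from every start, against 5.82 in length-matched lists (2 to 10). Most of the 24 lacked a promoter peak, and of the 20 that did, 11 had one away, within the 5 to 14 of matched genes without a promoter peak. Of the erythroid, stem and progenitor genes without a promoter peak, 9 of 9 had one away, against 4.73 in such lists (2 to 8). The polycomb and methylation count was also high, so a raised count is not seen at the erythroid, stem and progenitor genes alone. The megakaryocyte, myeloid and lymphoid genes among the 24 are of blood lineages too. The difference between the groups was not tested.

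Gene length does not account for the count at the haematopoietic genes. Random lists of listed genes with the same lengths had 7.47 such genes on average (middle 95%, 3 to 12), and the observed 28 was at their 100th percentile. Among the 22 that also had a promoter peak, 19 had one, against 3.26 in matched lists (0 to 7), and 11 of the 31 had a summit over 5 kb from every listed start, against 3.08 (0 to 7). Starts that the table does not list remain open. Of the 61 pairs of gene and summit, 8.20% had the summit beyond the gene's end, so most positions could hold another start of the same gene. Whether these are enhancers or further promoters cannot be told apart here, since no other mark was measured.

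The tall peaks on chromosome 22 lay in 1 stretch of 4.01 Mb, from DGCR6 to PRAME, and 23 of the 50 widest peaks were in it. K562 cells carry extra copies of the BCR-ABL1 fusion and its neighbourhood, and a candidate explanation is that the stretch holds extra DNA that raises every peak in it. Its 34 promoter peaks had a median height of 78.5 against 28 elsewhere, a ratio of 2.80. Promoter height defined the stretch, so the promoter ratio was high by construction. The 6 peaks of the stretch with a summit over 1 kb from a listed start had 59 against 24. Their ratio of 2.46 goes with extra copies. They were wide (median 5918 bp against 714 bp), but 4 had no base within 1 kb of a listed start. These 4 also had a median of 59. Stronger occupancy of the listed promoters alone is argued against, since 0% of 2183 overlapping windows of 6 consecutive such peaks elsewhere reached that ratio (middle 95%, 0.79 to 1.35), nor did any of 371 separate windows. Starts that the table does not list, the copy number itself and the scaling of the input were not analysed here.

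Promoter summits lay downstream of the start on both strands, with a median of 84 bp for genes on the plus strand and 114 bp for genes on the minus strand. A fixed shift of positions along the chromosome would give opposite signs, and the smaller value, 84 bp, argues against it as the whole cause. A listed start that is the most upstream of several would leave no shift at genes with 1 listed transcript. Those 553 summits had a median of 68 bp (bootstrap 95% interval 52 to 91 bp), above the 32 bp bound set for them, so it may add to the shift without being all of it. Starts missing from the table at single-transcript genes remain untested.

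Starts on both strands within 1 kb of the summit were found for 26.3% (23.3 to 29.4%) of promoter peaks with a height of at least 46 and 17.2% (16.3 to 18.2%) of those below. Relative to protein-coding genes in the reference names, chromosome X had 15.4 peaks per 100 genes and chromosome 13 had 29.3, against 60.1 on chromosome 16 and 57.9 on chromosome 6. These densities were not corrected for the copy number of the chromosomes, which was not analysed, so they do not measure differences in occupancy.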
